A study of Mus musculus with 65 samples.

How the data were processed

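Genomic DNA of mouse hepatocytes was extracted with a DNeasy kit, regions around each cut site were amplified by PCR with Phusion Flash polymerase, amplicons of a sample were pooled in equal amounts and libraries were prepared with NEBNext Ultra II, per the labels' protocols. The submitters' processing notes name bcl2fastq, R 4.2.1, Bowtie2, deepTools and the mouse build mm10, without saying what each was used for; the tool that set the junction of each read is not given in the sources used here. Each of the 67 deposited tables holds 1 line per read, with the last template base matched before the junction, the first matched after it, the matching read positions, a net indel length and a microhomology length, per the file headers. These are positions and lengths in bp and not normalised values. In every table the indel length equals the template gap minus the read gap, so that deletions are positive and insertions negative, and the microhomology length equals the overlap of both matched parts in the read. All junctions span 1 template position per site, taken here as the cut, so indels elsewhere in the amplicon are not seen, and reads with no indel are kept in the tables.

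Reads were grouped by arm, site and time from the labels. At Tfam-sg2-3 each sample has a second table of some of the same reads against a template 53 bp shorter; the table on the full template was used and the second left out. A read counted as an indel read where its net length was not 0. Shares were given with exact (Clopper-Pearson) 95% intervals and differences with Newcombe intervals. A site with no indel reads would allow a share of up to 3 reads of its total, between 0.0107% and 0.131% over these libraries. Depth ran from 2290 to 27974 reads; shares of the sequencer's 2 tiles differed by at most 2.63 points within a library, and 2 of 65 libraries differed between tiles at an unadjusted Fisher p under 0.05, against 3.25 by chance.

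Libraries were compared with two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over 21 sites against EV, over 20 time comparisons, over 8 comparisons of PTG and coinjection and over 14 comparisons of the frameshift share, at a threshold of 0.05. Exact sign-flip tests used targets or sites as units. The labels do not say whether sites come from the same animal, so these units may not be independent. The EV reference was the library of the same site at 2 wpi. The similarity of spectra was tested by 100000 permutations of site labels. All 9 targets and 21 sites are named; single alleles are named only from the 3 with the most reads in the earliest sgRNA library of a site (coinjection at 2 wpi for Lats sites), each with at least 1% of its reads, a rule set before the data were examined. Gene positions come from the RefSeq annotation of GRCm38.p6, the assembly called mm10, where 8 of the 9 targets matched by symbol; EGFP is a transgene. No amplicon sequences were used, so cut sites are not placed in exons.

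Alternatives set before the data were examined left out alleles with under 2 or under 10 reads, kept only indels within 5 bp of the cut, counted 1 bp indels as unedited or left them out, counted equal-length replacements as edited, subtracted the EV share, left out the most frequent allele, counted each allele once, moved the microhomology minimum from 2 bp to 1 or 3 bp, used 1 minus Pearson's r as the distance, took the PTG arm at the Lats sites, took the site as the unit, and left out each target in turn. Chosen after seeing the data were leaving out sites with a library under 5000 reads, leaving out Tfam-sg2-3, and taking 2 and 3 wpi apart in the mean of PTG minus coinjection. The Fisher test with its adjustment was tested on simulated data at the depths of the EV libraries with a base share of 40%: it called 0 of 210 comparisons with no difference, 76.7% with a difference of 2 points and 99.0% with 5 points. The simulated reads were independent, without PCR copies or differences between animals. These rates therefore check the calculation and do not give the error rate for the real libraries. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.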

Results

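Hepatocytes were taken from mice whose Rosa locus carries a Cre-dependent Cas9 and EGFP cassette and which had received an adeno-associated virus (AAV) by retro-orbital injection. The virus carried either an empty sgRNA cassette (EV) or sgRNAs against a target gene. The region around each cut site was amplified from genomic DNA and sequenced, so that each read reports the sequence left at the cut site of 1 amplified molecule. Altogether 65 libraries covered 21 cut sites of 9 targets, with 21 EV libraries and 44 sgRNA libraries. The sgRNA libraries fall into an arm labelled KO (1 library at 1 week post injection (wpi), 17 at 2, 3 at 3 and 3 at 8 wpi), an arm labelled coinjection (4 libraries each at 2 and 3 wpi) and an arm labelled PTG (4 libraries each at 2, 3 and 6 wpi); the last 2 arms hold the 4 Lats1 and Lats2 sites, and the labels do not spell out PTG. A library held between 2290 and 27974 reads (median 12621), 828461 in all. Each combination of arm, site and time is 1 library, so there is no measure of the spread between animals. Intervals below are exact 95% binomial intervals for shares and Newcombe intervals for differences; they cover counting error only, because reads without molecular identifiers are not independent molecules. Fisher's exact tests compare 2 libraries and not 2 conditions.

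The first question was how much of each target was edited against the empty vector. Every one of the 21 sites had a higher indel share with its sgRNA at 2 wpi than in its EV library (Fisher's exact test, two-sided, adjusted over 21 sites). In the KO arm the indel share had a median of 89.8% over 17 sites, with 12 sites above 80% and 8 above 90%, and ran from 25.6% at Tfam-sg1 to 97.2% at Tfam-sg2-3. The 4 coinjection libraries lay between 39.4% and 50.96%. In the EV libraries the share had a median of 0.111% and ran from 0.0219% at Hnf4a-sg1 to 0.699% at Kif11-sg2. Averaged over the sites of each target, the difference was 73.5 ± 20.2 percentage points (SD over 9 targets) and above 0 for 9 of 9 targets (exact sign-flip test, two-sided, p = 0.00391, the smallest this number of targets allows). Counting 1 bp indels as unedited lowered that mean to 30.1 points. By the most frequent read end, with indel lengths allowed for, reads of the EV libraries ended 2 bp later than those of the sgRNA libraries at 21 of 21 sites, and among unedited reads at 20 of 21 (1 bp at Tfam-sg2-3), so this comparison also runs between libraries with different read ends.

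**Figure D1:**
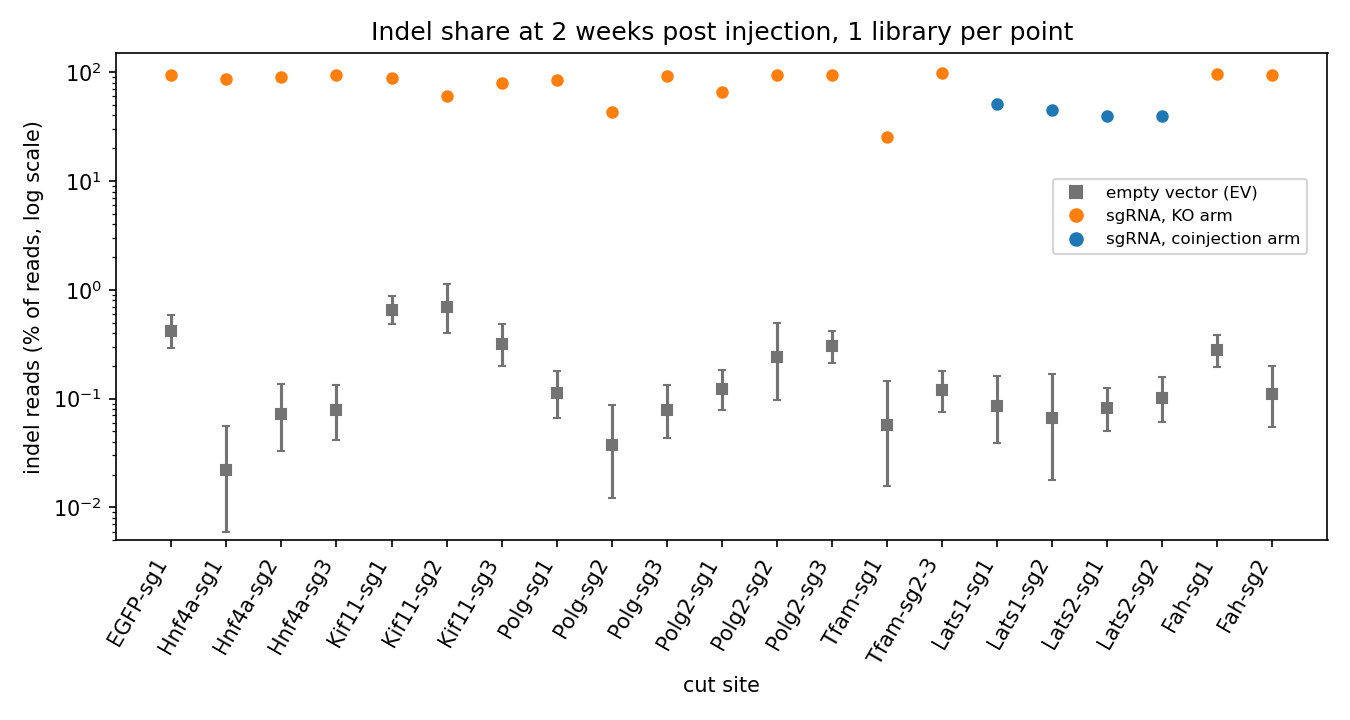
Indel reads as a percent of all reads (log axis) at each of the 21 cut sites at 2 wpi, with EV libraries as squares and sgRNA libraries as circles (orange for the KO arm, blue for the coinjection arm) and bars for exact 95% binomial intervals. The EV libraries lie between 0.0219% and 0.699% and the sgRNA libraries between 25.6% and 97.2%.

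EGFP, the reporter in the Rosa cassette, was cut at 1 site, with 94.6% indel reads at 2 wpi (95% interval 94.2 to 95.03) against 0.418% in EV. Hnf4a, a nuclear receptor that drives hepatocyte gene expression (chromosome 2, 163506811 to 163572907, mm10), had 85.8%, 89.8% and 93.8% at sg1, sg2 and sg3. Fah, the last enzyme of tyrosine breakdown (chromosome 7, 84585159 to 84605942), had 96.6% at sg1 and 94.8% at sg2. Kif11, a kinesin of the mitotic spindle (chromosome 19, 37376382 to 37421863), had 88.7% at sg1, 59.8% at sg2 and 79.3% at sg3.

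Polg, the catalytic subunit of the mitochondrial DNA polymerase (chromosome 7, 79446231 to 79467911), had 84.5%, 43.3% and 92.7% at sg1, sg2 and sg3, a range of 49.4 points. Polg2, its accessory subunit (chromosome 11, 106768204 to 106779537), had 65.3%, 94.6% and 95.2%, a range of 29.8 points. Tfam, which binds and packages mitochondrial DNA (chromosome 10, 71225468 to 71238328), had 25.6% at sg1 and 97.2% at the amplicon named for sg2 and sg3; the 71.7 points between them compare 1 sgRNA with an amplicon named for 2. The ranges were 28.9 points for Kif11, 7.98 for Hnf4a and 1.85 for Fah, and in coinjection 6.05 for Lats1 and 0.445 for Lats2. In PTG at 2 wpi Lats1-sg1 had 55.2% and Lats1-sg2 9.65%. Over the 21 sites the exact interval of the sgRNA library reached a median of 0.635 points to either side of the share, and at most 1.54 points. The positions of the cut sites within the genes are not analysed here.

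At Tfam-sg2-3 the indels were mostly deletions of about 1 length. A deletion of 50 to 60 bp was present in 89.4% of KO reads (89.0 to 89.9) and in 0.104% of EV reads. The deletion of 53 bp with clean edges held 50.9% of KO reads and that of 54 bp held 32.6%, and the 1 bp insertion held 4.25%. The second template of this site is shorter by 53 bp, the length of the leading deletion. The labels do not give the cut positions or say which sgRNAs 1 virus carried.

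EGFP-sg1 was measured at 1, 2 and 3 wpi, with 1 library per time. A change over time therefore cannot be told apart from a difference between animals or samples. The indel share rose from 61.5% at 1 wpi (60.5 to 62.5) to 94.6% at 2 wpi, a rise of 33.2 points (32.1 to 34.3). From 2 to 3 wpi it fell by 0.950 points, to 93.7% (interval of the difference -1.52 to -0.382; Fisher's exact test, two-sided, adjusted p = 0.00108 over 20 time comparisons). Counting only indels within 5 bp of the cut turned this small difference to 1.09 points upward. The 1 bp insertion at the cut held 27.4%, 44.9% and 44.5% of reads at 1, 2 and 3 wpi, and the leading 1 bp deletion held 10.05%, 10.6% and 11.5%.

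Kif11 was measured at 2 and 8 wpi, with 1 library per site and time, so time and animal cannot be told apart here either. The indel share at sg2 rose from 59.8% to 90.8%, by 31.1 points (29.9 to 32.3), and at sg3 from 79.3% to 86.4%, by 7.09 points (5.32 to 8.86). At sg1 it fell by 1.60 points, from 88.7% to 87.1%. All 3 differences passed Fisher's exact test after adjustment, but over the 3 sites the mean of 12.2 ± 16.9 points (SD) had an exact sign-flip p = 0.50, where the smallest possible is 0.25. The 3 sites ended between 86.4% and 90.8%. The 1 bp insertion at sg2 rose with the indel share, from 23.2% to 35.6% of reads, while its share of indel reads was 38.9% at 2 wpi and 39.2% at 8 wpi.

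Fah was measured at 2 and 3 wpi, again with 1 library per site and time and the same limit. At sg1 the share rose by 0.694 points to 97.3% (0.340 to 1.05; adjusted p = 0.000127) and at sg2 by 2.80 points to 97.6% (2.24 to 3.38; adjusted p = 1.3e-22), both by Fisher's exact test, two-sided. With 1 bp indels counted as unedited the differences were -2.24 points at sg1, past the threshold, and -0.939 at sg2, not past it (Fisher's exact test, adjusted p = 0.147). At sg1 the leading allele was a 1 bp deletion, in 34.1% and 37.6% of reads at 2 and 3 wpi, and at sg2 a 1 bp insertion, in 59.1% and 64.2%.

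Lats1 (chromosome 10, 7681200 to 7716461) and Lats2 (chromosome 14, 57689662 to 57746212) encode kinases of the Hippo pathway, and their sites were sequenced after coinjection and in the PTG arm. At 2 wpi the indel share at Lats1-sg1 was 55.2% in PTG and 50.96% in coinjection, a difference of 4.22 points (2.84 to 5.59). At the other sites PTG was lower. Lats1-sg2 had 9.65% against 44.9%, Lats2-sg1 5.79% against 39.4% and Lats2-sg2 5.90% against 39.8%. Distinct indel alleles there numbered 45, 20 and 25 in PTG, against 81, 72 and 60 in coinjection. The PTG shares may thus rest on few amplified molecules, which tests on reads do not cover. At 3 wpi Lats1-sg1 had 63.7% in PTG against 40.7%, a difference of 22.9 points (21.1 to 24.7), while the others had 15.5% against 38.2%, 11.8% against 33.3% and 16.9% against 35.4%. PTG was thus lower in 6 of 8 comparisons and higher in 2, each past Fisher's exact test adjusted over 8. Averaged over 2 and 3 wpi, the mean difference over the 4 sites was -17.3 ± 20.6 points (SD; exact sign-flip p = 0.25, a test that cannot reach 0.05 with 4 sites); it was -24.6 points at 2 wpi and -9.95 at 3 wpi. With 1 bp indels counted as unedited, the Lats1-sg1 difference was -0.111 points at 2 wpi and 0.420 points at 3 wpi, neither past the threshold.

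From 2 to 3 wpi the libraries of the arms moved in opposite directions. The labels do not say whether the 4 sites of an arm and time come from 1 animal. The joint falls or rises may therefore reflect a single difference between animals. In coinjection the share fell between 2 and 3 wpi by 10.2 points at Lats1-sg1, by 6.73 at Lats1-sg2, by 6.10 at Lats2-sg1 and by 4.43 at Lats2-sg2. In PTG it rose by 8.48, 5.84, 5.98 and 10.996 points at the same sites. By 6 wpi it had risen further at 3 of the 4 PTG sites, to 26.2% at Lats1-sg2, 24.4% at Lats2-sg1 and 35.5% at Lats2-sg2, while at Lats1-sg1 it stood at 43.7%, 11.4 points below its value at 2 wpi (difference -11.4, interval -12.9 to -9.94). All 12 differences passed Fisher's exact test after adjustment. In PTG, Lats1-sg2, Lats2-sg1 and Lats2-sg2 held 45, 20 and 25 distinct indel alleles at 2 wpi and 154, 102 and 67 at 6 wpi. The rises there may thus rest partly on few amplified molecules at 2 wpi, which tests on reads do not cover. With 1 bp indels counted as unedited, 2 of the 4 falls in coinjection passed the threshold and the rise at Lats1-sg1 in PTG turned to -0.213 points. For 3 against 2 wpi the exact sign-flip test over 4 sites gave the smallest p it allows in either arm, which does not reach 0.05, and for 6 against 2 wpi in PTG it gave 0.25.

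**Figure D2:**
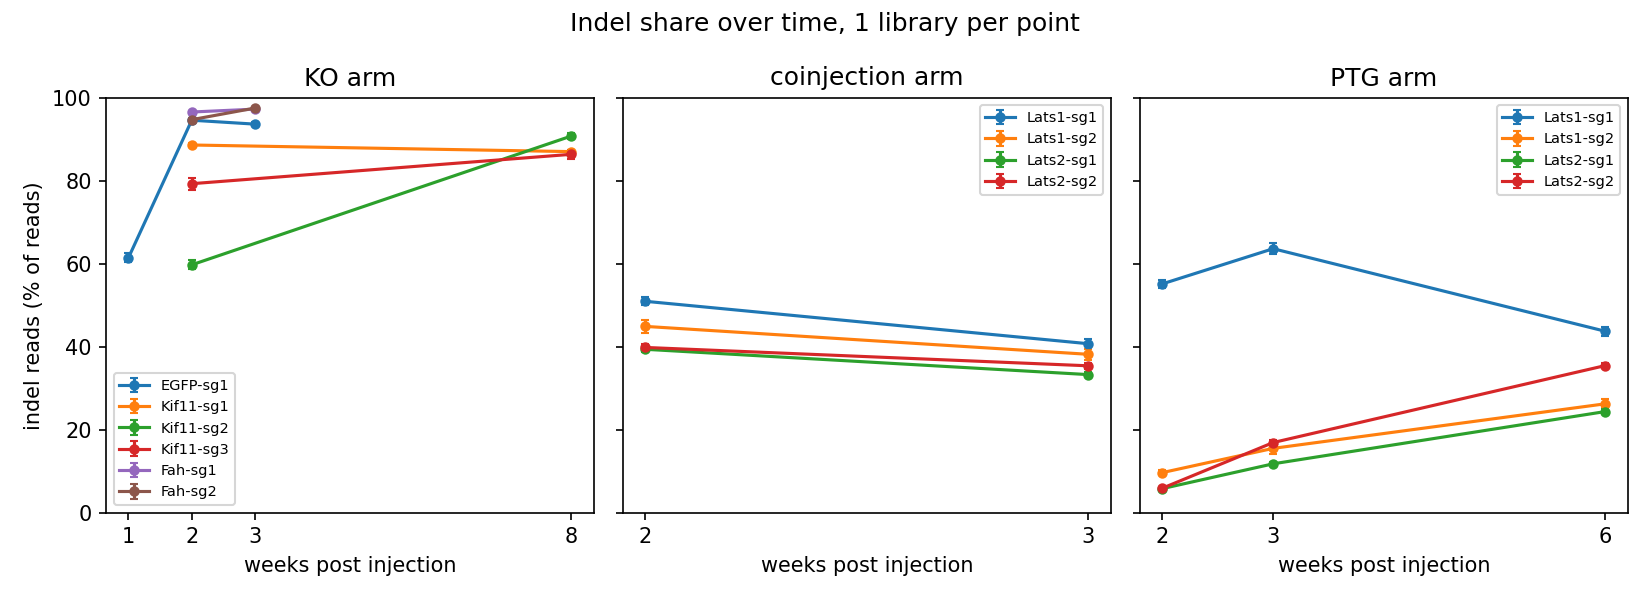
Indel reads as a percent of all reads against weeks post injection for sites measured more than once, in the KO, coinjection and PTG arms; each point is 1 library and bars are exact 95% binomial intervals. In the PTG panel Lats1-sg1 starts at 55.2% and ends at 43.7%, and Lats2-sg2 goes from 5.90% to 35.5%.

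The kinds of indel differed from site to site. Insertions made up a median of 62.5% of indel reads over the 44 sgRNA libraries (4.99% to 92.7%), and 13 of 21 sites had more insertion than deletion reads at 2 wpi. The median was 26.5% without 1 bp indels and 26.4% without the most frequent allele of each library. The most frequent indel length was a 1 bp insertion at 14 of 21 sites. The single 1 bp insertion at the cut held 77.3% of reads at Hnf4a-sg3, 78.8% at Polg2-sg3, 69.5% at Polg-sg3, 56.4% at Kif11-sg1 and 51.1% at Polg2-sg1. The leading allele was a 1 bp deletion at Hnf4a-sg1 (19.3% of reads), Polg2-sg2 (32.1%) and Fah-sg1 (34.1%), and a 2 bp deletion at Hnf4a-sg2 (38.2%) and Lats1-sg2 (22.1% in coinjection at 2 wpi). Insertions of 20 bp or more took 18.6% of indel reads at Hnf4a-sg1, 14.3% at Hnf4a-sg2 and 12.7% at Kif11-sg1.

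**Figure D3:**
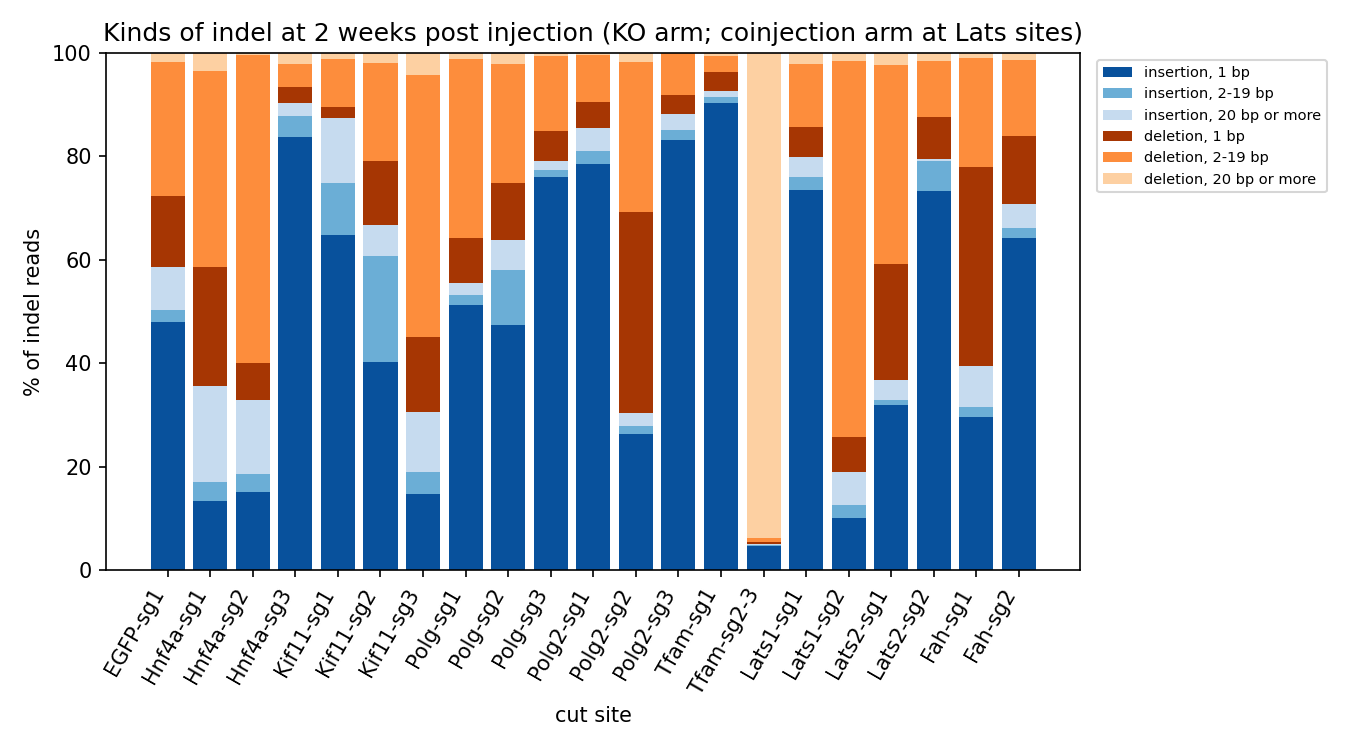
Kinds of indel as a percent of indel reads at each cut site at 2 wpi (KO arm, coinjection arm at Lats sites), stacked to 100%, with insertions in blue and deletions in orange shades by length. Insertions of 1 bp take 90.3% at Tfam-sg1 and 4.57% at Tfam-sg2-3, where deletions of 20 bp or more take 93.7%.

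Indels whose length is not a multiple of 3 shift the reading frame where the cut lies in coding sequence, which was not checked. The frameshift share here is the share of indel reads with such lengths. They made up a median of 92.7% of indel reads over the 44 sgRNA libraries, and the interval lay above 66.7%, the value if all lengths modulo 3 were equally frequent, in 43 of them. The exception was Tfam-sg2-3 at 63.2% (62.5 to 63.99), where the deletion of 54 bp, a multiple of 3, held 33.5% of indel reads. The highest was Tfam-sg1 at 99.1%. Counting each distinct allele once gave a median of 71.2%. Between the first and last time of a site, 9 of 14 comparisons of the frameshift share passed Fisher's exact test (two-sided, adjusted over 14), 5 upward and 4 downward. At Kif11 the change from 2 to 8 wpi was 1.94 points at sg1 and -3.03 at sg3, both past the threshold. The frameshift share at Lats2-sg1 in PTG fell by 10.4 points, from 96.8% at 2 wpi to 86.4% at 6 wpi, and at Lats1-sg2 in PTG it fell by 8.78 points, from 90.8% to 82.0%. It rose at Lats1-sg2 in coinjection from 84.6% to 89.9%, by 5.35 points, and at Lats2-sg1 in coinjection by 3.17 points. Other changes at the Lats sites that passed were 3.90 points at Lats2-sg2 and 1.05 at Lats1-sg1 in PTG, and -3.96 at Lats2-sg2 in coinjection. The first of these was lost without 1 bp indels (-5.06 points; Fisher's exact test, adjusted p = 0.139) and without the most frequent allele (2.66; adjusted p = 0.257). At EGFP-sg1 the difference of 3 against 1 wpi was -0.923 points (-1.85 to 0.0391; Fisher's exact test, adjusted p = 0.0784), but -1.78 without alleles under 10 reads (adjusted p = 0.000316) and -2.73 without the most frequent allele (adjusted p = 0.00368). Without alleles under 10 reads 12 of 14 comparisons passed. In PTG the indel reads of Lats2-sg1 held 20 distinct alleles at 2 wpi and 102 at 6 wpi, and those of Lats2-sg2 held 25 and 67. The shares at 2 wpi may thus rest on few amplified molecules. The tests on reads cannot tell the changes at these sites from sampling of molecules.

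Deletions of 2 bp or more with at least 2 bp of microhomology at the junction made up a median of 9.87% of such deletions. The share was 74.7% at Hnf4a-sg2 (73.6 to 75.7), 64.4% at Polg-sg3 (62.4 to 66.4) and 55.2% at Polg2-sg1 (52.4 to 58.04), where the 2 bp deletion with 2 bp of microhomology held 38.2%, 8.60% and 3.02% of reads. That allele made up 4675 of 4920, 1366 of 1434 and 591 of 672 deletion reads with such microhomology. The high shares at these sites thus rest mainly on 1 allele each. The microhomology share was 1.29% at Tfam-sg2-3, against 1 of 20 reads in the EV library of that site (0.127 to 24.9), the one EV library with 20 or more deletions of 2 bp or more.

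Indel spectra resembled each other more within a site than between sites. Over the 33 libraries of 10 sites measured more than once, the mean total variation distance between indel-length distributions (0 for identical, 1 for disjoint) was 0.153 over 48 pairs from 1 site and 0.422 over 480 pairs from different sites, a difference of -0.269 (permutation test with 100000 permutations of site labels, two-sided, p = 1e-05, the smallest they can give). Without 1 bp indels the difference was -0.140, still past the threshold. Single pairs overlapped, with distances from 0.0503 to 0.312 within a site and from 0.0930 to 0.756 between sites. Each Lats site gave 10 of the 48 pairs within a site, so these sites weigh most. Within Lats1-sg1 the distances had a median of 0.0821 over 10 pairs, and within Lats2-sg1 0.253.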

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

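The tests of the ratios at the Lats sites were chosen after the results were seen. Differences between effects carry 95% counting intervals in which no bound reached 0, and they compare libraries, not animals.

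The effect of PTG against coinjection differed between Lats sites. At 2 wpi it was 39.5 points higher at Lats1-sg1 than at Lats1-sg2, 37.8 higher than at Lats2-sg1 and 38.1 higher than at Lats2-sg2; at 3 wpi these gaps were 45.6, 44.4 and 41.4 points. The change from 2 to 3 wpi was higher in PTG than in coinjection by 18.7 points at Lats1-sg1, 12.6 at Lats1-sg2, 12.1 at Lats2-sg1 and 15.4 at Lats2-sg2. From 2 to 6 wpi in PTG the change was 28.03 points higher at Lats1-sg2, 30.03 at Lats2-sg1 and 41.01 at Lats2-sg2 than at Lats1-sg1.

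A lower share of edited cells in the PTG sample, as the only cause, would lower all 4 sites by 1 factor. At 2 wpi the ratio of PTG to coinjection at Lats1-sg1 was 5.04 times the next highest (4.63 to 5.48). Within counting error of reads, this argues against a lower share of edited cells as the only cause. The ratios were 0.215 at Lats1-sg2, 0.147 at Lats2-sg1 and 0.148 at Lats2-sg2. A lower share of edited cells, with Lats1-sg1 differing for another reason, stays open. In coinjection the ratios of 3 to 2 wpi differed by at most 1.11 times over the 4 sites (1.06 to 1.16). This is beyond counting error but within the limit set for 1 common factor, such as a different animal or DNA sample, so that factor stays open. In PTG they differed by 2.48 times, over the limit. This spread cannot decide the question, because Lats1-sg1, at 55.2% at 2 wpi, could not rise by the 2.86 times of Lats2-sg2. Lats2-sg1 and Lats2-sg2 started at 5.79% and 5.90% and rose 2.03 times (1.90 to 2.17) and 2.86 times (2.68 to 3.06). These intervals cover counting error of reads only. The libraries at 2 wpi held 20 and 25 distinct indel alleles, so the ratios may rest on few amplified molecules. They therefore cannot decide on 1 common factor for those sites either. The bound on this spread was first written over both arms and then read per arm. What sets the sites apart in PTG was not tested, and differences between animals that vary from site to site were not measured, as there are no replicate libraries.

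The change from 2 to 8 wpi at Kif11-sg2 was 32.7 points higher than at Kif11-sg1 and 23.98 points higher than at Kif11-sg3.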

How the results depend on the processing

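Leaving out sites with a library under 5000 reads, leaving out Tfam-sg2-3 and taking 2 and 3 wpi apart in the mean of PTG minus coinjection were chosen after seeing the data. The count of 21 sites above EV held under every alternative run on all sites (17 of 17 without low-depth sites). The mean over targets kept its sign and its side of the threshold, from 70.8 to 77.8 points with 1 target left out. As reported, EV shares were at most 0.699% and sgRNA shares at 2 wpi at least 25.6%, so the alternatives were a weak check of either. The distance within minus between sites ran from -0.343 to -0.192 with the sites of 1 target left out, was -0.140 without 1 bp indels and -0.185 without the most frequent allele, and stayed past the threshold. With 1 bp indels counted as unedited, 0 of 2 Fah sites rose (Fah-sg1 -2.24 points, Fah-sg2 -0.939, not past the threshold), 2 of 4 coinjection sites fell (Lats2-sg2 0.381), Lats1-sg1 in PTG changed by -0.213 from 2 to 3 wpi, and PTG minus coinjection there at 2 wpi was -0.111. By its construction this setting drops the leading allele at many sites. With indels within 5 bp of the cut, EGFP-sg1 at 3 minus 2 wpi was 1.09 points; the cause was not tested. The median frameshift share was 93.4% without alleles under 10 reads, 94.2% within 5 bp, 76.8% without 1 bp indels, 81.5% without the most frequent allele and 71.2% with each allele once. The median insertion share was 70.3% within 5 bp, 26.5% without 1 bp indels, 26.4% without the most frequent allele and 63.8% without Tfam-sg2-3. The median microhomology share was 5.36% within 5 bp, 20.3% with a minimum of 1 bp and 2.98% with 3 bp; leaving out 1 bp indels cannot change it. Changes in frameshift share passed the threshold, unlike as reported, at EGFP-sg1 without alleles under 10 reads (-1.78) and without the most frequent allele (-2.73), at Fah-sg2 in these settings (-1.24, -2.29) and without 1 bp indels (-3.31), and at Fah-sg1 within 5 bp (1.03). Of the changes that turned sign, 5 had not passed the threshold as reported: EGFP-sg1 0.408 points within 5 bp; Kif11-sg2 0.543 without alleles under 10 reads; Fah-sg1 -0.196 without 1 bp indels; Fah-sg2 0.0488 within 5 bp; Lats1-sg1 in coinjection 1.55 without alleles under 10 reads (past the threshold there), 3.38 without 1 bp indels and 1.41 without the most frequent allele. Lats2-sg2 in PTG, at 3.90 points, turned to -5.06 without 1 bp indels and was 2.66 without the most frequent allele, neither past the threshold. The causes were not tested. Depth limits the low-read libraries most: 2 EV and 5 sgRNA libraries held under 5000 reads.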

Other observations

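The tests of empty-vector reads and of chimeric amplicons were chosen after the results were seen, and so was the count of insertions that fit at every site; the relation to room was set before.

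The microhomology share differed between libraries at some sites, without a test. At EGFP-sg1 it was 2.79%, 9.39% and 4.66% at 1, 2 and 3 wpi, and at Lats1-sg2 8.22%, 11.2% and 22.8% at 2, 3 and 6 wpi in PTG and 14.6% and 9.86% at 2 and 3 wpi in coinjection. At Kif11 it was 12.9% and 12.2% at sg1, 9.04% and 9.88% at sg2 and 20.9% and 21.3% at sg3 at 2 and 8 wpi. At Lats2-sg1 in PTG it was 0% of 351 deletions at 2 wpi (up to 1.05%), 0.516% at 3 wpi and 21.4% at 6 wpi, and in coinjection 8.84% at 2 wpi and 4.36% at 3 wpi. At Lats2-sg2 in PTG it was 21.7%, 13.7% and 46.5% at 2, 3 and 6 wpi, and in coinjection 15.5% and 27.6% at 2 and 3 wpi. The PTG libraries at 2 wpi held only 20 distinct indel alleles at Lats2-sg1 and 25 at Lats2-sg2. These shares may thus rest on few amplified molecules, which intervals on reads do not cover.

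Among 262414 EV reads, 377 carried an indel at the cut. Of the 115 with an indel of 2 bp or more, 59.1% had an allele that held at least 0.5% of the indel reads of the sgRNA library of the same site, against a mean of 13.1% for other sites (permutation test with 100000 permutations of site labels, p = 1e-05, the smallest they can give). The 53 bp and 54 bp deletions at Tfam-sg2-3 gave 11 and 8 of the 68 matching reads. The share without that site is not given here. Deletions of 10 bp or more and insertions of 20 bp or more made up 14.3% of EV indel reads, and 9.60% without Tfam-sg2-3, more than the 5% set as the limit for sequencing or polymerase errors as the only source. Of the EV indel reads 97.1% ended where unedited EV reads end (94.8 to 98.5) and 2 of 377 where sgRNA reads end, which argues against reads mixed in with the read end of the sgRNA libraries. Carry-over of DNA or amplicons of the same site before the read end was set may be the source, which the matching alleles fit, and stays open, as does a read end set per library by trimming; no biological explanation was tested.

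Insertions of 20 bp or more had a median length of 47 bp over 18373 reads of the sgRNA libraries and reached 203 bp. Pooled over sites at 2 wpi they held 4.45% of sgRNA library reads and 0.0103% of EV reads (27 reads), 433 times as much, and their share was higher with the sgRNA at 21 of 21 sites, which argues against chimeric amplicons formed without a cut. The ratio of medians, 731, rests on 1 read in the EV library at the median, as 10 of 21 EV libraries held none. Across 21 sites their share of indel reads rose with the room left in the longest read, with Spearman's rho 0.582 (permutation p = 0.00653) and Pearson's r 0.489 (permutation p = 0.0236). Without 2 sites far from the median room rho was 0.452 (permutation p = 0.0530) and r was 0.300 (permutation p = 0.214), neither past the threshold. Tfam-sg2-3 lay farthest, and Hnf4a-sg2 and Polg2-sg3 were tied as the next, of which only 1 was left out. The other choice was not run, so the call depends on which sites are kept. Only 6.74% of these insertions were longer than 113 bp, the length that fits at every site. Counting those up to 113 bp therefore could change little, and it kept 90.2% of the range over sites and a rho of 0.564 (permutation p = 0.00882). The limit of the read is thus not the whole difference, but an effect of length below that limit was not tested. The inserted sequences are not analysed here, and what they are stays open.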
